A study of Homo sapiens with 28 samples.

How the data were processed

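Gene expression was measured on 28 single-colour Affymetrix arrays of cells derived from the neuroblastoma line SK-N-AS, 21 of the line with doxycycline-inducible MYCN and 7 of a mock line. Per the labels, cells were grown in DMEM with fetal calf serum, doxycycline was added, and total RNA was isolated with Trizol, cleaned on RNeasy columns and checked on a Bioanalyzer; 4 µg per array was labelled in a single amplification cycle. The deposited values are intensity values on a linear scale, 1 per probe set and array; the submitters' processing notes name MAS5 and GCOS, the Affymetrix programs that summarise probes and scale each array, and their versions are not given in the sources used here. Tested on the deposited table itself, the mean signal after trimming 2% at either end was 100 in all arrays, as per-array scaling would give; no further normalization was applied. Replicates were not pooled. The median signal of an array was 12.9 to 20.2. No genome build was used here, and coordinates are not given.

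The table holds 54675 probe sets. By the platform annotation, 41091 named 1 gene, 1801 several and 11783 none; only the first kind was tested, and the 62 control probe sets were left out. Of the single-gene probe sets 41043 matched a current gene identifier. The 91 values at or under 0 were set to 0.1, the lowest positive value, and all values were taken to log2, written here as log2 of the deposited intensity. Each of 19775 genes was represented by its probe set with the highest mean log2 signal, so probe sets of a gene that disagree are seen only through the alternatives below. Genes at or above the 40th percentile of mean log2 signal over all arrays (3.68, a signal of 12.8) were tested, which left 11865 genes, 60% of those with a probe set. Small MAS5 signals scatter widely on the log scale, so folds of dim genes are uncertain.

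All statistics used R 4.3.3 and limma 3.58.1 (lmFit, eBayes with trend). Each time was compared with time 0 in a single fit of the 21 arrays of the MYCN line (14 residual degrees of freedom), with a moderated F-test over the 6 contrasts beside it. The mock line has 1 array per time, so no time could be tested alone: a linear trend on the time step, 0 to 6 in the order of the times, was fitted to its 7 arrays (5 residual degrees of freedom). The difference in trend was the interaction of line and time step over all 28 arrays (24 residual degrees of freedom). P-values were two-sided, adjusted by Benjamini-Hochberg over the genes tested, and called under 0.05. Time 0 arrays are shared by all contrasts, so overlaps between times were not compared.

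A total of 20 gene lists with 470 genes (MYC network, ribosome biogenesis, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, nucleotide, polyamine and one-carbon synthesis, glycolysis, chaperones, G1/S and DNA replication, mitosis, p53 targets, noradrenergic, mesenchymal and Schwann cell markers, extracellular matrix and adhesion, antigen presentation by MHC class I, interferon response, cholesterol synthesis, amino acid and endoplasmic reticulum stress, immediate early genes, hypoxia) was tested with camera at a preset correlation of 0.01, adjusted over 160 tests of lists by contrasts. fry, a second limma list test, called 1, 4, 9, 10, 12 and 13 lists at the 6 times, 5 for the mock trend and 14 for the difference in trend. These were not always the same lists: fry called 53 of the 67 that camera called. At time 4 its single call was the MYC network, which holds MYCN itself. With a correlation estimated for each list, 0 of the 67 calls held (limma camera; 34 of 160 tests had an unadjusted p under 0.05). Numbers of members past the threshold are given adjusted over all genes and adjusted over the list alone. The tests, the filter, the lists and the rule for named genes were chosen before the data were examined. The rule named MYCN, MYC and MAX; per time the 4 genes with the largest increase and the 4 with the largest decrease among those past the threshold whose 3 arrays all lay beyond the 3 of time 0; the 4 members of each list with the smallest F-test p-value; and the 5 genes with the most positive and the 5 with the most negative difference in trend.

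Signals of the spiked hybridisation controls split the arrays into 2 batches: bioD read 1544 to 1941 in replicates 1 and 2 of the MYCN line, and 2322 to 2770 in its replicate 3 and the mock line. Batch effects were therefore examined with the batch as a block and within a batch. Whether replicate numbers pair the arrays was checked from the data, since the labels give only the numbers: deviations from the group means correlated with those of the time 0 array of the same number at 0.200, 0.188 and 0.323 at time 4, 0.241, 0.246 and 0.367 at time 8, and 0.149, 0.129 and 0.226 at time 192 (replicates 1, 2 and 3), all above 0.1, but fell to -0.0608 at time 24, 0.0549 at time 48 and -0.0248 at time 96 for replicate 2. The numbers were taken to pair the arrays at times 4, 8 and 192. Replicate 3 was the only array of the line in its batch at each time, so the batch alone could also give such correlations. No pair of the 28 arrays was a duplicate: at most 1.59% of probe sets shared a value, and the highest correlation was 0.936.

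Alternatives were quantile normalization, equal array medians, an offset of 3.9 before the log, no filter or a filter at the 60th percentile, the mean of a gene's probe sets, leaving out probe sets with the suffixes _s_at and _x_at, eBayes without trend, the replicate number as a block, a fit to the compared times alone, other forms of the trend, and leaving out replicates and single arrays. Added after seeing the data were the hybridisation batch as a block or alone, the ACTB 3' to 5' ratio as a covariate, the difference in trend without time 192, and the lists without the mock array of time 192, with equal medians or with MYCN left out. On simulated data with 200 changed genes among 11865, the contrast of time 192 recovered 33%, 64% and 90% of genes changed by 0.5, 1 and 2 (log2), with 8.33% false among its 120 calls. The F-test recovered 19%, 62% and 86%, the mock trend 13%, 50% and 92%, and the difference in trend 6%, 54% and 82%. For the trend tests these sizes were total changes over the 6 time steps, not changes per step. Of 20 simulated lists, the 5 shifted by 0.3 and 0 of the others were called by limma's camera. The simulated genes varied independently, so this does not test the preset correlation for lists whose members vary together.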

Results

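SK-N-AS is an established human neuroblastoma cell line without MYCN amplification. RNA from 2 derivatives of this line was measured on 28 microarrays. In the MYCN line, doxycycline switches on a MYCN transgene, and 21 arrays followed it at 7 times after the drug (labels 0, 4, 8, 24, 48, 96 and 192, with the unit of time not stated), with 3 replicates at each time. The mock line carries the vector for the tet repressor and was also harvested after doxycycline, with 1 array at each of the same 7 times. The comparisons ask how the transcriptome changes as MYCN is induced and whether those changes differ from what happens in the mock line. Beyond naming time courses in triplicate, the labels do not say that arrays came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. Changes are log2 differences with their standard error (SE), and all tests were two-sided.

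MYCN, the transcription factor that the system induces, was measured by its brightest probe set. Its signal was 84 ± 17.5 (SD, n = 3) at time 0, 2168 ± 820 at time 4, 4571 ± 259 at time 48 and 3193 ± 112 at time 192. MYCN had risen by 4.65 (SE 0.17) at time 4 and by 5.79 at time 48 (limma adjusted p = 7.76e-13 and 1.22e-14), with all arrays above those of time 0. In the mock line the same probe set read 1.6 to 3 at all 7 times, which is background. The other 9 MYCN probe sets stayed at or under 32.7 in all arrays, with a median of 2.7. When probe sets with the suffixes _s_at and _x_at, which can match several transcripts, were left out, MYCN was read by a probe set with group means of 5.3 to 12.8 in the MYCN line, near background, and its change was negative (-1.45 to -0.03) but not called at any of the 6 times (adjusted p = 0.237 to 0.986).

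MYC, the family member that SK-N-AS cells express, fell as MYCN rose. Its signal was 221 ± 88.7 at time 0 and 68.4 ± 58.1 at time 192 in the MYCN line, against 256 and 298 in the mock line. The MYC change passed the test at times 48 (-2.04, SE 0.48), 96 (-2.10) and 192 (-1.93, limma adjusted p = 0.00566). MAX, the partner through which MYC proteins bind DNA, rose by 0.37 (SE 0.07) at time 192 (limma adjusted p = 7.64e-04), and MXI1, a MYC antagonist, rose by 1.35 (SE 0.18). At time 192 the MYC call ended without replicate 2 (-2.01) or replicate 3 (-1.48). The MAX call ended with equal array medians (0.39), with the mean of all probe sets (0.20) and without the _s_at and _x_at probe sets (0.04).

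**Figure D1:**
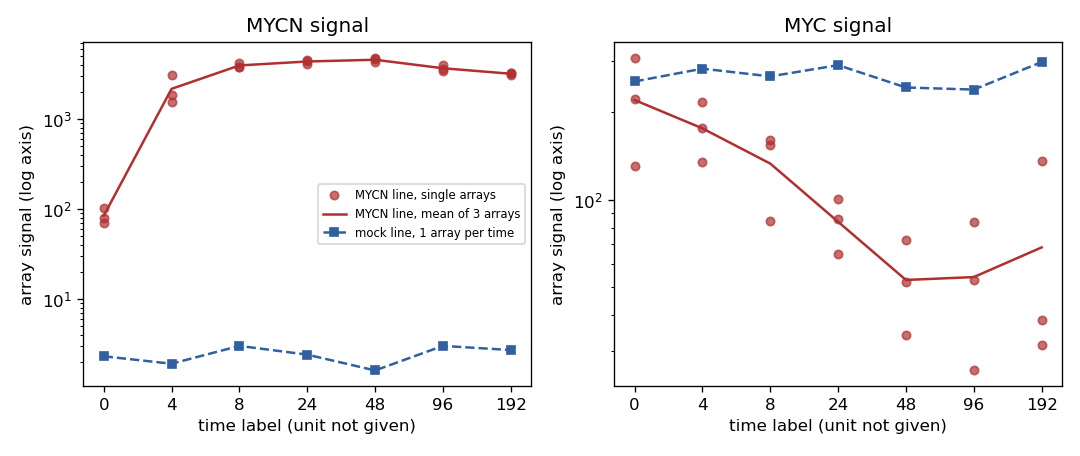
Signal of MYCN (brightest probe set, left) and MYC (right) on a log axis against the time label, whose unit is not given. Points are single arrays of the MYCN line, lines the means of 3 arrays, and squares the single mock arrays. MYCN rises from a mean of 84 to 3193 and MYC falls from 221 to 68.4 between times 0 and 192.

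At time 4, MYCN itself was the single gene past the threshold among the 11865 tested. Small list shifts were called, and for 3 of the 5 lists the mock array of that time moved at least as far. Genes of nucleotide, polyamine and one-carbon synthesis (median 0.07), ribosome biogenesis (0.05) and mitochondrial ribosomal proteins (0.06) shifted upward against other genes. The adjusted p of camera, limma's test of a list against the other genes, was 9.16e-04, 0.00160 and 0.00251 in that order, and the adjusted p = 0.121, 0.384 and 0.328 with an estimated correlation. Cholesterol synthesis (median 0.11, adjusted p = 0.0488) and DNA replication genes (0.04, adjusted p = 0.0339) shifted the same way, with adjusted p = 0.672 and 0.436 with an estimated correlation. Both calls ended with quantile normalization (adjusted p = 0.106 and 0.162) and that of the DNA replication genes also with equal medians (0.110). In the single mock array of time 4 the medians of these lists were 0.09, -0.05, 0.05, 0.20 and 0.08 in the order of naming, so ribosome biogenesis alone moved the other way there. In these 5 lists 0 members passed limma's test over all genes, and 4, 3, 1, 0 and 4 had an unadjusted p under 0.05 in the order of naming. Adjusted over the list alone, 1 DNA replication gene was lower. limma's fry called none of these 5 lists (adjusted p = 0.0505, 0.355, 0.214, 0.637 and 0.449 in the order of naming). Over all genes 778 had an unadjusted p under 0.05. With the replicate number as a block 12 genes were called, with the hybridisation batch as a block 3, and within batch 1 (replicates 1 and 2) 1. Batch 2 holds 1 array of the line per time and gives no test. Without the replicate 1 array of time 0, or that of replicate 1 or 3 at time 4, the count was 2.

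At time 8 the first wider response appeared. PER2, a repressor of the circadian clock, rose by 1.31 (SE 0.12, limma adjusted p = 9.05e-06), from a signal of 63.2 ± 2.3 to 158 ± 25.2. DDN, which encodes the cytoskeletal protein dendrin, rose by 2.41 (SE 0.54), the amino acid transporter SLC6A15 by 0.96 (SE 0.17), and the ornithine decarboxylase ODC1, which makes polyamines, by 0.45. HAS2, a hyaluronan synthase (-1.20, SE 0.27, adjusted p = 0.0404), PNRC1, a nuclear receptor coactivator (-0.98, SE 0.18), and the RNA-binding protein gene RBM15 (-0.66, SE 0.13) fell. The mock array of time 8 moved in the same direction, by 0.40 for PER2, -0.21 for HAS2, -0.23 for PNRC1 and -0.31 for RBM15, whereas DDN was lower there (-0.22). Of the ribosome biogenesis genes 3 of 25 rose (5 adjusted over the list alone), among them WDR12 (0.42) and POLR1B (0.52). The list shifted upward with a median of 0.14 and a camera adjusted p = 1.23e-06, or adjusted p = 0.175 with an estimated correlation.

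Further lists moved at time 8. Nucleotide, polyamine and one-carbon synthesis (2 of 24 rose, 3 adjusted over the list alone, median 0.05, adjusted p = 0.00430, and adjusted p = 0.163 with an estimated correlation) and mitochondrial ribosomal proteins (0 of 29 past limma's threshold, 4 higher and 1 lower at an unadjusted p under 0.05, median 0.07, adjusted p = 0.00846, and adjusted p = 0.396 with an estimated correlation) shifted upward, the latter not with equal medians (adjusted p = 0.119). The MYC network list, which holds MYCN itself, was called upward with 2 of 11 higher (3 adjusted over the list alone, adjusted p = 0.0119, and adjusted p = 0.146 with an estimated correlation), although its median was -0.03 and its mean 0.47. Without MYCN, an alternative chosen after the data were seen, the other 10 genes were not called (median -0.05, adjusted p = 0.551), so this call restates the induction. Interferon response genes (median -0.23, adjusted p = 1.93e-04, and adjusted p = 0.121 with an estimated correlation), DNA replication genes (-0.06, 0.00277 and, with an estimated correlation, adjusted p = 0.290) and extracellular matrix genes (-0.13, 0.0306 and, with an estimated correlation, adjusted p = 0.273) shifted downward. In these 3 lists 0 members passed limma's test over all genes. Adjusted over the list alone 4 of 19 interferon and 3 of 33 replication genes were lower, and 5, 9 and 2 of the members were lower at an unadjusted p under 0.05. In the mock array of time 8 the medians were -0.17 for extracellular matrix and 0.08 for mitochondrial ribosomal proteins, as large as in the MYCN line, against -0.02 for interferon response, 0.05 for DNA replication, 0.01 for nucleotide synthesis and -0.06 for ribosome biogenesis. With the replicate number as a block, cholesterol synthesis (median 0.24, 0.18 in the mock array, adjusted p = 0.0274) and chaperones (0.05 and 0.08, adjusted p = 0.0472) were also called upward at time 8. Without the block, where neither was called, they had adjusted p = 0.683 and 0.529 with an estimated correlation. Cholesterol synthesis was also called with the batch as a block (0.0280) and with equal medians (0.0191). In limma's fry the calls of mitochondrial ribosomal proteins, DNA replication and extracellular matrix at time 8 did not hold (adjusted p = 0.151, 0.055 and 0.0648).

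The PER2 call at time 8 ended with the mean of probe sets (0.17), as did that of RBM15 (-0.13), and with equal medians the calls of HAS2 (-1.23), PNRC1 (-1.01) and RBM15 (-0.69) ended. In all, 91 genes were called at time 8, 70 higher and 21 lower, of which 9 changed at least 2-fold. Of the higher genes 68.6% were also higher in the mock array of time 8 (median 0.11, against 0.61 in the MYCN line), and of the lower genes 100% were also lower (-0.21 against -0.59). Of all tested genes 49.2% were higher in that mock array. With the replicate number as a block the count was 280, with the hybridisation batch as a block 219 and within batch 1 (without replicate 3) 21. With equal array medians 10 genes were called, all higher. The count fell to 4 without replicate 1 and to 2 without replicate 2. The calls of DDN, HAS2 and RBM15 at this time ended without any single array of times 0 and 8 except, for RBM15, the replicate 2 array of time 0. The PNRC1 call ended without the replicate 3 array of time 0 (-0.99) or time 8 (-0.72).

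At time 24 the response had widened to 852 genes, 464 higher and 388 lower, 126 of them by at least 2-fold. ABCA17P, a transcribed pseudogene, rose by 2.51 (SE 0.26, limma adjusted p = 7.28e-06), SLC6A15 by 2.01 (SE 0.17) and PER2 by 1.84 (SE 0.12). TP53INP1, a p53 target (-2.75, SE 0.42, adjusted p = 4.69e-04), the growth factor binding protein gene IGFBP5 (-2.57, SE 0.46), and LAMP5, a lysosomal membrane protein of neurons (-3.29, SE 0.92, adjusted p = 0.035), fell. At that time the signals of TP53INP1 (6.97) and LAMP5 (9.50) were under 12.8, so the size of their falls is uncertain. The lists called upward were chaperones (5 of 19 rose, 9 adjusted over the list alone), mitochondrial ribosomal proteins (7 of 29, 9 over the list alone), nucleotide, polyamine and one-carbon synthesis (4 of 24 rose and 1 fell, 9 and 1 over the list alone), ribosome biogenesis (4 of 25, 5 over the list alone) and the MYC network (3 of 11 rose and 1 fell, 5 and 3 over the list alone). Their camera adjusted p was 3.62e-07, 2.57e-06, 2.26e-06, 3.89e-05 and 0.0260, and the adjusted p = 0.121, 0.160, 0.0575, 0.273 and 0.175 with an estimated correlation. The MYC network call at time 24 restates the induction of MYCN, since it ended without that gene (median -0.09, adjusted p = 0.419). Interferon response genes (5 of 19 fell, 8 adjusted over the list alone) and extracellular matrix genes (1 of 27, 2 over the list alone) were called downward, with adjusted p = 2.56e-05 and 0.0300. The adjusted p = 0.0825 and 0.273 with an estimated correlation. The extracellular matrix median was -0.13 in the MYCN line and -0.10 in the mock array of time 24, and the chaperone median 0.16 and 0.10.

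With the hybridisation batch as a block 1604 genes were called at time 24, and 656 within batch 1. Equal array medians gave 294, the mean of probe sets 518 and probe sets without the suffixes _s_at and _x_at 561. The count was 195 without replicate 1, 164 without replicate 2, 429 and 543 without the replicate 1 or 2 array of time 24, and 555 without the replicate 3 array of time 0. The call of TP53INP1 ended without replicate 2 (-2.14), that of IGFBP5 without replicate 1 (-2.50), and that of LAMP5 without several single arrays, of which replicate 1 of time 24 left the smallest change (-2.48).

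At time 48, 1745 genes were called, 835 higher and 910 lower, and 335 changed at least 2-fold. LINC03095, a long noncoding RNA (-3.17, SE 0.35, limma adjusted p = 1.06e-05), RET, a receptor tyrosine kinase of sympathetic neuroblasts (-2.59, SE 0.77), and FN1, which encodes fibronectin (-1.55, SE 0.27), had fallen. Chaperone genes were the list with the smallest p (8 of 19 rose, 13 adjusted over the list alone, camera adjusted p = 3.44e-09, and adjusted p = 0.0694 with an estimated correlation). Ribosome biogenesis (11 of 25 rose, 12 over the list alone), mitochondrial ribosomal proteins (12 of 29 rose and 1 fell, 18 and 2 over the list alone) and nucleotide, polyamine and one-carbon synthesis (11 of 24 rose and 1 fell, 13 and 1 over the list alone) shifted upward with adjusted p = 4.03e-06, 1.04e-06 and 1.27e-06. They had adjusted p = 0.213, 0.146 and 0.0575 with an estimated correlation. Glycolysis (3 of 18 rose and 1 fell, 4 and 1 over the list alone, adjusted p = 0.0110, and adjusted p = 0.277 with an estimated correlation) and the MYC network (3 of 11 rose and 2 fell, 5 and 2 over the list alone, adjusted p = 0.0487, and adjusted p = 0.239 with an estimated correlation) were also called upward, the latter not with quantile normalization (adjusted p = 0.0682) or with the batch as a block (adjusted p = 0.0504). The MYC network median was 0.10, and without MYCN it was -0.06 and the call ended (adjusted p = 0.474). Interferon response (8 of 19 fell, 13 over the list alone) and extracellular matrix genes (5 of 27, 6 over the list alone) were called downward with adjusted p = 6.77e-06 and 0.0462. The adjusted p = 0.0694 and 0.280 with an estimated correlation. The extracellular matrix median of the mock array at time 48 (-0.14) was lower than that of the MYCN line (-0.10).

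With the batch as a block 2696 genes were called at time 48 and 2173 within batch 1. Equal medians gave 821, the mean of probe sets 1125, probe sets without the suffixes _s_at and _x_at 1108, and a fit to the arrays of times 0 and 48 alone 544. The count was 359 without replicate 1, 241 without replicate 2, 940 and 963 without the replicate 1 or 2 array of time 48, and 1121 without the replicate 3 array of time 0.

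**Figure D2:**
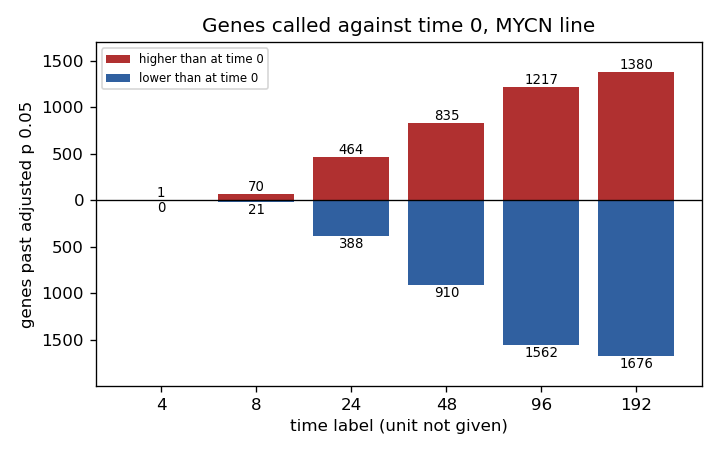
Genes past an adjusted p of 0.05 in limma against time 0, per time label (unit not given), in the MYCN line. Bars above the axis count genes with higher signal and bars below it genes with lower signal, from 1 and 0 at time 4 to 1380 and 1676 at time 192. With equal array medians the totals at times 8, 24, 48, 96 and 192 were 10, 294, 821, 1567 and 1886.

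At times 96 and 192 several genes had fallen far below their signal at time 0. TAC1, the precursor of substance P, changed by -4.49 (SE 0.68) at time 96 and by -5.40 at time 192 (limma adjusted p = 1.40e-05), from a signal of 1542 ± 268 at time 0 to 44.3 ± 34.8. The complement gene C7 changed by -6.33 (SE 1.03) and -5.94, the Golgi kinase gene GASK1B by -3.89 (SE 0.30) and -5.21, RET by -4.13 (SE 0.77) and -4.86, and the tubulin gene TUBB2B by -3.06 (SE 0.95) and -5.33. LAMP5 fell at time 96 to a signal of 1.13, at background, so the size of its change (-5.77) was not measurable. The signal of C7 at time 96 (6.60) and at time 192 the signals of C7 (4.17), GASK1B (5.47) and TUBB2B (6.37) lay below 12.8, the mean signal at which genes were filtered, so the size of these falls is uncertain. Among the largest rises, TKTL1, a transketolase-like gene, rose by 3.21 (SE 0.67) and 3.54, and GPAT3, an acyltransferase of glycerolipid synthesis, by 2.66 (SE 0.60) and 3.47. HMOX1, the stress-induced heme oxygenase, passed the test at time 192 (3.42, SE 0.54, adjusted p = 1.39e-04), with a signal of 721 ± 624 (SD, n = 3). TKTL1's call at time 96 ended without replicate 2 (3.14).

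In all, 2779 genes were called at time 96 (1217 higher and 1562 lower, 621 by at least 2-fold) and 3056 at time 192 (1380 and 1676, 746 by at least 2-fold). Of the latter, 190 higher and 556 lower genes changed at least 2-fold. With the hybridisation batch as a block the counts were 3791 and 3999, and within batch 1 they were 2794 and 2972. They were 1567 and 1886 with equal medians, 1449 and 1543 without replicate 1, and 787 and 1327 without replicate 2. At time 96, probe sets without the suffixes _s_at and _x_at gave 1844. A moderated F-test over the 6 times called 3011 genes (limma), 4498 with the batch as a block and 2951 within batch 1. It called 1629 with equal medians, 857 without replicate 1 and 687 without replicate 2.

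At time 192 gene groups of biosynthesis were higher. Of the ribosome biogenesis genes 12 of 25 rose (18 adjusted over the list alone), with a median of 0.31 and a camera adjusted p = 1.28e-06, or adjusted p = 0.175 with an estimated correlation. Among them RRP9, a component of the nucleolar U3 particle, rose by 1.48 (SE 0.18) and WDR12 by 0.53 (SE 0.07). TCOF1, a nucleolar protein gene, was higher by 0.37, a call that ended in several settings and turned to -0.25 without the _s_at and _x_at probe sets. Of the mitochondrial ribosomal protein genes 16 of 29 rose and 1 fell (17 and 1 over the list alone, median 0.30, adjusted p = 1.04e-06, and adjusted p = 0.146 with an estimated correlation), with MRPS30 higher by 0.72 (SE 0.12) and MRPL17 lower (-0.46, SE 0.08, not called with equal medians, -0.43). Of the nucleotide, polyamine and one-carbon genes 11 of 24 rose and 1 fell (13 and 1 over the list alone, median 0.26, adjusted p = 3.68e-06, and adjusted p = 0.0575 with an estimated correlation). ODC1 rose by 0.96 (SE 0.08, limma adjusted p = 1.25e-07), the mitochondrial folate enzyme gene MTHFD2 by 0.64 (SE 0.10), and the purine synthesis gene PPAT by 0.73, a rise that was gone (-0.0012) without the _s_at and _x_at probe sets. Of the chaperone genes 9 of 19 rose (10 over the list alone, median 0.17, adjusted p = 1.80e-05, and adjusted p = 0.175 with an estimated correlation), including FKBP4 (0.85, SE 0.12) and mitochondrial HSPA9 (0.60, SE 0.07). In the same order the list medians were 0.36, 0.26, 0.34 and 0.18 within batch 1 and 0.16, 0.23, 0.33 and 0.19 in replicate 3, the single array of batch 2. In the mock array of time 192 they were -0.27, -0.22, -0.31 and -0.11.

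Stress and growth factor response lists also moved upward at time 192. Of the amino acid and endoplasmic reticulum stress genes 8 of 18 rose (9 over the list alone, median 0.55, adjusted p = 3.36e-04, and adjusted p = 0.280 with an estimated correlation). SLC7A5, which imports large neutral amino acids, rose by 2.20 (SE 0.31), and the cystine transporter SLC7A11 by 2.21 (SE 0.44), with a signal of 356 ± 291 and a call that ended without replicate 2 (2.17). Of the immediate early genes 6 of 17 rose and 1 fell (6 and 1 over the list alone, median 0.16, adjusted p = 0.0436, and adjusted p = 0.423 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.0535) and without replicate 2. The phosphatase gene DUSP5 rose by 2.15 (SE 0.37) and the transcription factor gene JUN by 1.39 (SE 0.24), the latter without a call when _s_at and _x_at probe sets were left out (0.75). The medians of these lists within batch 1 were 0.41 and 0.13, and in replicate 3 they were 0.43 and 0.19. In the mock array of time 192 they were 0.21 and -0.07. Against the mean of time 0 the amino acid and endoplasmic reticulum stress median was 0.83 in replicate 1, but 0.28 and 0.23 in replicates 2 and 3, close to the mock value. Against its own time 0 array, as the mock value is taken, replicate 3 was at 0.43.

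Cholesterol synthesis, interferon response and extracellular matrix genes were lower at time 192. Of the cholesterol genes 10 of 14 fell (all 14 adjusted over the list alone), with a median of -0.80 and a camera adjusted p = 7.91e-07, or adjusted p = 0.273 with an estimated correlation. The sterol carrier gene STARD4 (-1.64, SE 0.16, limma adjusted p = 1.06e-06), INSIG1, the sterol-regulated anchor of the SREBP pathway (-1.58, SE 0.27), and IDI1, an isomerase of the mevalonate pathway (-1.12, SE 0.14), fell. The median of this list was 0.11 at time 4, 0.24 at time 8, -0.24 at time 24, -0.34 at time 48 and -0.59 at time 96 (0.20, 0.18, 0.24, 0.17 and 0.09 in the mock arrays). Against time 0 of the same number the fall began at different times, with replicate 2 at -0.61 by time 24, replicate 1 at -0.54 by time 48 and replicate 3 still at 0.11 at time 48. At time 96 the list was called (5 of 14 fell, 9 over the list alone, adjusted p = 0.00107, and adjusted p = 0.441 with an estimated correlation). Of the interferon response genes 12 of 19 fell (13 over the list alone, median -0.64, adjusted p = 5.92e-06, and adjusted p = 0.0694 with an estimated correlation), among them IFI44 (-1.44, SE 0.20), IRF9 (-1.10, SE 0.17), a subunit of the interferon-stimulated transcription factor, and IFI35 (-0.89, SE 0.11). Of the extracellular matrix genes 11 of 27 fell and 2 rose (12 and 2 over the list alone, median -0.32, adjusted p = 0.0104, and adjusted p = 0.175 with an estimated correlation). FN1 (-2.99, SE 0.27) and the fibrillar collagen gene COL3A1 (-1.21, SE 0.18) fell. This list's call ended without replicate 3. The medians of these lists were -0.82, -0.76 and -0.24 within batch 1 and -0.79, -0.61 and -0.48 in replicate 3, against -0.03, 0.21 and 0.08 in the mock array of time 192. The IDI1 call ended without the _s_at and _x_at probe sets (-0.12).

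Most of these lists had already been called at time 96, with ribosome biogenesis (9 of 25 rose, 9 adjusted over the list alone, adjusted p = 1.04e-04), mitochondrial ribosomal proteins (17 rose and 1 fell, 20 and 2 over the list alone, 1.04e-06), nucleotide synthesis (10 and 1, 13 and 1 over the list alone, 7.54e-06), chaperones (9, 10 over the list alone, 5.69e-06), amino acid and endoplasmic reticulum stress (4 and 1, 4 and 1 over the list alone, 0.0326), immediate early (5 of 17, 7 over the list alone, 0.00567), interferon response (10 of 19 fell, 12 over the list alone, 1.44e-04) and extracellular matrix (8 of 27 fell, 10 over the list alone, 0.0110). In that order the adjusted p = 0.280, 0.146, 0.0575, 0.163, 0.494, 0.290, 0.121 and 0.175 with an estimated correlation. The extracellular matrix median at time 96 was -0.22 in the MYCN line and -0.11 in the mock array. The amino acid stress call at time 96 ended with quantile normalization (adjusted p = 0.0614).

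**Figure D3:**
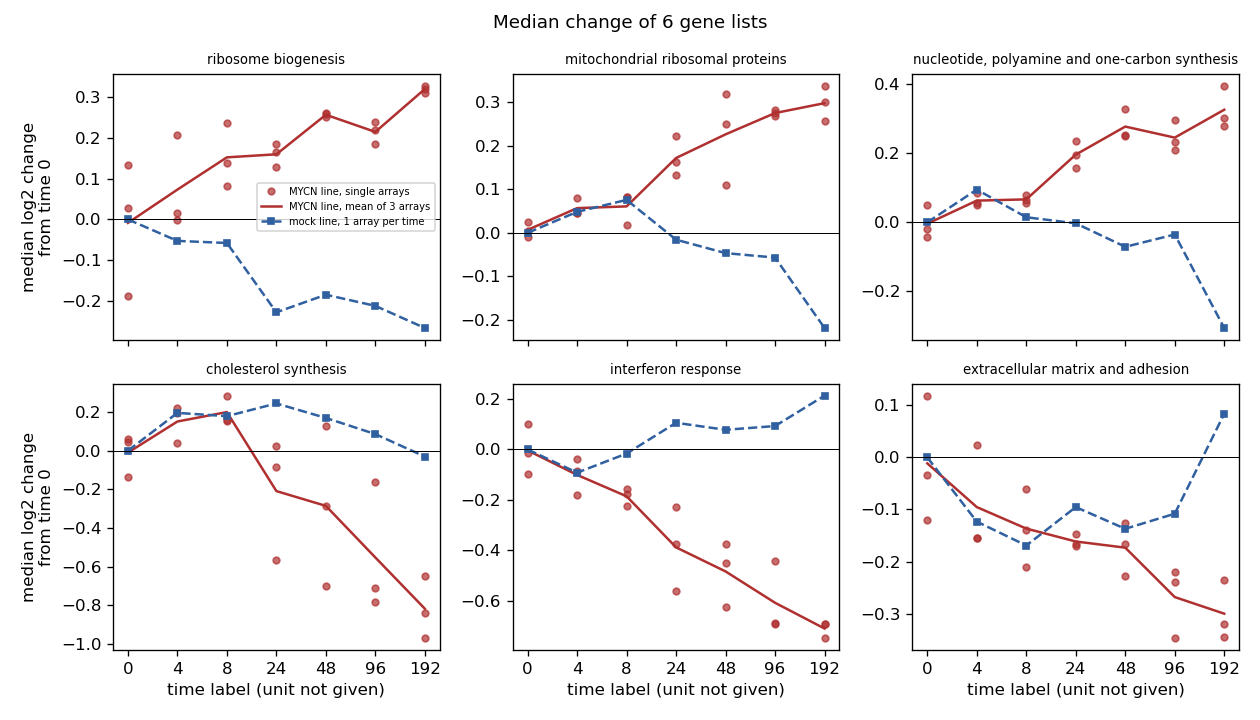
Median log2 change from time 0 of 6 gene lists against the time label (unit not given). Red points are single arrays of the MYCN line against the mean of its time 0 arrays, red lines the means of 3 arrays, and blue squares the single mock arrays against the mock array of time 0. At time 192 the lists of ribosome biogenesis, mitochondrial ribosomal proteins and nucleotide synthesis lie above 0 in the MYCN line and below 0 in the mock line.

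The other 11 lists were not called at time 192, and counts adjusted over the list alone stand first in the parentheses. Cell cycle genes varied singly: of the G1/S and DNA replication genes 1 of 33 rose, the cyclin gene CCNE1 (0.67, not called with the mean of probe sets, 0.64), and 3 fell (1 and 2 over the list alone, camera adjusted p = 0.615). Of the mitosis genes 4 of 27 fell (4, adjusted p = 0.340), with KIF20A at -0.70. Of the p53 targets 1 of 19 rose and 5 fell (2 and 6, adjusted p = 0.297). PLK2, a polo-like kinase (-2.12, SE 0.22), and DDB2, a DNA damage sensor (-1.05, SE 0.16), fell. Glycolysis had 6 of 18 higher and 2 lower (8 and 2, adjusted p = 0.0558, or 0.0279 with quantile normalization), with hexokinase HK2 higher by 1.13 (SE 0.17) and the aldolase gene ALDOC lower (-1.42, SE 0.34). Hypoxia response genes had 8 of 19 higher and 3 lower (9 and 5, adjusted p = 0.181), and the MYC network 4 of 11 higher and 3 lower (5 and 3, adjusted p = 0.0878, or 0.490 without MYCN). Noradrenergic markers had 2 of 12 higher and 5 lower (2 and 5, adjusted p = 0.470) and mesenchymal markers 3 of 21 higher and 4 lower (5 and 6, adjusted p = 0.915). The noradrenergic median was 0.03 within batch 1 and -0.61 in replicate 3. In the mesenchymal list the receptors PDGFRA (-2.69, SE 0.33) and PDGFRB (-1.72, SE 0.26) fell and the hyaluronan receptor CD44 rose (1.37, SE 0.31). The CD44 call and that of ALDOC ended without replicate 2 (1.36 and -1.20). The mesenchymal median was 0.07, its mean -0.04 and its test pointed upward. Antigen presentation had 1 of 15 higher and 2 lower (1 and 2, adjusted p = 0.304), and cytosolic ribosomal proteins 1 of 20 lower, RPS9 (-0.21), with 0 lower in limma's adjustment over the list alone and 1 at an unadjusted p under 0.05 (adjusted p = 0.240). The RPS9 call ended with equal medians (-0.18), with the mean of probe sets (-0.20), in a fit to times 0 and 192 alone (-0.21), and without replicate 2 (-0.21), replicate 3 (-0.14) or the replicate 3 array of time 0 (-0.17) or 192 (-0.17). Of 9 Schwann cell markers with a probe set 2 passed the signal filter, L1CAM (0.41) and MBP (0.25), and neither passed the test (adjusted p = 0.671 for the list).

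Changes with time in the mock line depended strongly on the analysis. A linear trend over its 7 arrays, in log2 per time step, was called in 371 genes, 191 rising and 180 falling (limma). HK2 (-0.15, SE 0.03), SLC7A5 (-0.16, SE 0.04) and SLC7A11 (-0.21, SE 0.05) fell in this line, and RET (0.15, SE 0.03) and TAC1 (0.33, SE 0.05) rose. The ribosome biogenesis list shifted downward against other genes (4 of 25 fell, 8 adjusted over the list alone, median -0.043, camera adjusted p = 3.18e-06, and adjusted p = 0.0962 with an estimated correlation), as did mitochondrial ribosomal proteins (1 of 29, 5 over the list alone, adjusted p = 2.65e-05), nucleotide synthesis (2 of 24, 9 over the list alone, adjusted p = 5.66e-04), glycolysis (3 of 18, 5 over the list alone, adjusted p = 0.0138), mitosis (2 of 27, 2 over the list alone, adjusted p = 0.0168) and chaperones (1 of 19, 1 over the list alone, adjusted p = 0.0207). With an estimated correlation these had adjusted p = 0.376, 0.273, 0.169, 0.423 and 0.529. G1/S and DNA replication genes also shifted downward (adjusted p = 0.0101, and adjusted p = 0.672 with an estimated correlation), with 0 of 33 past limma's threshold and 7 at an unadjusted p under 0.05, 1 of them rising. Upward shifts were called for interferon response (1 of 19, 3 over the list alone, adjusted p = 0.0285), cytosolic ribosomal proteins (3 over the list alone, adjusted p = 2.24e-05) and antigen presentation (6 over the list alone, adjusted p = 0.0277), with adjusted p = 0.290, 0.476 and 0.436 with an estimated correlation. In the latter pair 0 members passed over all genes (limma), with 10 and 7 at an unadjusted p under 0.05.

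With the ACTB ratio as a covariate 0 genes were called for the mock trend (limma, 699 at an unadjusted p under 0.05), which ended the calls of HK2, SLC7A5, SLC7A11, RET and TAC1. In the mock arrays that ratio was lowest at time 0 (0.41) and highest at time 192 (0.64), so the covariate overlaps with time. Losing the calls therefore cannot show whether RNA quality caused the trend. The count was 3 with eBayes without trend, 2 for late minus early times, 83 on log2(time + 1), 154 without a filter, 112 with the mean of probe sets and 235 without the _s_at and _x_at probe sets. The last mock array, time 192, had the highest ratio of 3' to 5' signal for ACTB, 0.64 (log2), against 0.41 to 0.53 in the other mock arrays and 0.14 to 0.39 in the MYCN line. The count was 93 without that array, 943 without the array of time 0, 0 without that of time 4 (limma, with 2023 at an unadjusted p under 0.05), 54, 136 and 209 without those of times 8, 24 and 48, and 219 (60 rising and 159 falling) with equal medians. Without the array of time 192 the calls of antigen presentation, interferon response, chaperones and DNA replication ended, the last turning to a median of 0.007. Quantile normalization ended those of chaperones, mitosis and interferon response (adjusted p = 0.0535, 0.219 and 0.0671), and equal medians that of cytosolic ribosomal proteins (adjusted p = 0.0752).

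The trends of the MYCN line and the mock line differed in 2850 genes, 1329 with a more positive and 1521 with a more negative slope in the MYCN line (limma interaction of line and time step over all 28 arrays). The mock line has 1 array per time, so spread between repeated courses of that line was not measured and is not in these p-values. Already at time 0 the lines differed by at least 2 (log2) in 335 genes within batch 2, so slopes can start from unlike levels. GPAT3 rose by 0.61 per time step in the MYCN line against -0.14 in the mock line (difference 0.76, SE 0.18, adjusted p = 0.00318), and CCN3, a matricellular protein gene, had a difference of 0.68 (SE 0.12). TAC1 had slopes of -0.97 and 0.33 (difference -1.30, SE 0.18, adjusted p = 9.74e-06). Its signal at time 0 was 40.3 in the mock array, against 1275 to 1811 in the MYCN line. RET had slopes of -0.85 and 0.15, and C7 (difference -1.27, SE 0.29), the collagen gene COL26A1 (-0.98, SE 0.24) and the neuroendocrine granule gene CHGA (-0.97, SE 0.26) also had more negative slopes. Among genes called higher at time 192 the median change was 0.53 in the MYCN line and -0.14 in the mock line, and among those called lower it was -0.75 and 0.14. The mock array of time 192 is the one with the highest ACTB ratio. For genes called at times 24, 48 and 96 the mock medians at the same time were 0.05, -0.0058 and -0.03 for the higher and -0.09, -0.0039 and 0.03 for the lower genes. With the batch as a block 3401 genes were called and within batch 2 alone (MYCN replicate 3 and the mock arrays) 1963. In that batch the GPAT3 call ended (0.73), and without the mock array of time 192 those of COL26A1 (-0.79) and CHGA (-0.87). For late minus early times the C7 call ended (-4.12). The count was 1295 without the mock array of time 192, 1456 without time 192 in either line, 1690 for late minus early times and 1874 without the _s_at and _x_at probe sets, and with equal medians 1289 slopes were more positive and 813 more negative.

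By list, ribosome biogenesis (14 of 25 more positive, 16 adjusted over the list alone, camera adjusted p = 1.74e-08), mitochondrial ribosomal proteins (18 of 29, 1 more negative, 20 and 1 over the list alone, 3.44e-09), nucleotide synthesis (15 of 24, 1 more negative, 18 and 1 over the list alone, 1.08e-07) and chaperones (11 of 19, 14 over the list alone, 1.04e-06) had more positive slopes in the MYCN line. These lists had adjusted p = 0.0694, 0.0694, 0.0575 and 0.175 with an estimated correlation. So did glycolysis (7 of 18, 2 more negative, 9 and 3 over the list alone, 0.00251), immediate early (6 of 17, 9 over the list alone, 0.00461) and amino acid and endoplasmic reticulum stress genes (4 of 18, 4 over the list alone, 0.0168), with adjusted p = 0.152, 0.278 and 0.396 with an estimated correlation. Slopes were more negative for interferon response (10 of 19, 12 over the list alone, adjusted p = 1.09e-05), cholesterol synthesis (7 of 14, 9 over the list alone, 4.22e-04), cytosolic ribosomal proteins (5 of 20, 5 over the list alone, 4.22e-04), antigen presentation (6 of 15, 1 more positive, 6 and 1 over the list alone, 0.0221) and extracellular matrix (12 of 27, 2 more positive, 14 and 2 over the list alone, 0.0436). For these the adjusted p = 0.0575, 0.406, 0.511, 0.273 and 0.273 with an estimated correlation. The calls of antigen presentation and extracellular matrix ended without the mock array of time 192 (adjusted p = 0.147 and 0.270), and those of antigen presentation and cytosolic ribosomal proteins with equal medians (0.104 and 0.125).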

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

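The tests of the mock array at time 192, of line means removed, of time in culture and of all times of batch 2 were chosen after the result was seen, the others before their outcome was known.

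A test of the difference between the lines singled out 2850 genes and 10 named among them. More positive slopes in the MYCN line were seen for GPAT3 (0.76), DDN (0.75), PCOTH (0.73), the cytokine gene IL11 (0.71) and CCN3 (0.68), and more negative slopes for TAC1 (-1.30), C7 (-1.27), RET (-1), COL26A1 (-0.98) and CHGA (-0.97), all as log2 per time step. Without the mock array of time 192 the calls of DDN (0.60), PCOTH (0.45), IL11 (0.68), COL26A1 (-0.79) and CHGA (-0.87) ended, and within batch 2 those of GPAT3 (0.73), PCOTH (0.58) and IL11 (0.39). The same test singled out 12 lists, whose median differences per step were 0.051 for amino acid and endoplasmic reticulum stress, 0.06 for chaperones, 0.053 for glycolysis, 0.11 for immediate early genes, 0.091 for mitochondrial ribosomal proteins, 0.092 for nucleotide synthesis and 0.078 for ribosome biogenesis. With an estimated correlation 0 of the 12 were called (limma camera), while fry called 14 of all 20 lists. The other median differences were -0.064 for antigen presentation, -0.153 for cholesterol synthesis, -0.05 for cytosolic ribosomal proteins, -0.069 for extracellular matrix and -0.177 for interferon response.

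For the difference in trend, when the line label was reassigned within each time, 7 of 100 arrangements called at least 2850 genes and the highest other called 5916, so chance was not excluded by that test, and a count that large points to structure of the samples, here the differences between the lines; with each line first set to the same mean per gene, 1 of 100 did, the real one, and the highest other called 1427. A batch effect alone is argued against by the 1963 genes called within batch 2, where each line has 1 array per time. The mock array of time 192 alone is argued against as the whole cause for 10 lists, which were all still called without it and kept 88.5% of their size (median, with 59.9% for chaperones as the lowest and 147% as the highest, and 7 of 10 at or above 75%). It stays open for antigen presentation, which kept 78.56%, and extracellular matrix, which kept 59.7%, since both lost their call. Another clonal history of the mock line was not tested and may contribute to the remaining difference.

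The fall of cholesterol synthesis genes at time 192 was weighed against time in culture and RNA integrity. In the mock line these genes had a median trend of -0.00916 per time step (0.0213 without time 192), against -0.148 in the MYCN line. An effect of time in culture shared by both lines therefore does not account for the fall. The mock line gave 1 course and differed from the MYCN line at time 0, so an effect of culture time particular to the MYCN line stays open. With the ACTB ratio as a covariate the median at time 192 was -0.713 against -0.80. Within the MYCN line that ratio largely followed the batch, at 0.14 to 0.28 in replicates 1 and 2 and 0.29 to 0.39 in replicate 3. The covariate alone is therefore a weak test. From time 0 to time 192 the ratio fell in replicates 1 (0.25 to 0.16) and 2 (0.21 to 0.17) and rose slightly in replicate 3 (0.29 to 0.31). The list median changed alike in all 3, by -0.81, -0.83 and -0.79 against time 0 of the same number. These values argue against RNA integrity, as read by this ratio, as the cause of the fall. MYCN induction stays open as untested, since line and induction were varied together and the MYCN line was not followed here without doxycycline.

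Chance groupings of the arrays were examined for each count. For the single times 10 splits of 6 arrays exist, too few for a share under 0.05. The real counts and the highest of the other splits were 1 and 2 at time 4 (3 of 10 splits called at least 1), 91 and 0 at time 8, 852 and 0 at time 24, 1745 and 0 at time 48, 2779 and 0 at time 96, and 3056 and 2 at time 192. For the F-test 1 of 100 regroupings of the 21 arrays, the real one, called at least 3011 genes, and the highest other called 277. This argues against chance at that level, but the regroupings moved arrays freely across replicates and batches and did not keep that structure.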

How the results depend on the processing

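The hybridisation batch, the ACTB covariate, leaving out time 192, and, for lists, equal medians and leaving out MYCN or the mock array of time 192 were tests chosen after the results were seen. Apart from the values that follow, counts stayed within 1.5 times and named genes kept direction and side of the threshold in 1372 of the cases with other settings and 1022 of those leaving out arrays; 81 and 138 calls were lost, 10 and 2 gained, and 9 and 0 reversed. For the 20 lists at time 192 and in the difference in trend, 289 and 154 cases were unchanged in direction and side, 24 and 5 calls were lost and 7 and 1 gained. Over all 160 list tests 8 of the 67 calls were lost with quantile normalization, 5 with equal medians, 4 with MYCN left out, 1 with the batch as a block, and 8 without the mock array of time 192, where 3 were gained and 1 list turned direction. Where no cause is given, the cause was not tested.

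With equal array medians 10, 294, 821, 1567 and 1886 genes were called at times 8 to 192, 1629 by the F-test and 219 for the mock trend; higher calls were 100% at time 8 (76.9% before), 27.4% for the mock trend (51.5%) and 61.3% for the difference in trend (46.6%). Without a filter there were 57 at time 8 and 154 for the mock trend. With the mean of probe sets there were 0 at time 4 (limma; 690 unadjusted), 41, 518 and 1125 at times 8, 24 and 48, and 112 for the mock trend; CENPI at time 8 turned to 0.10. Without _s_at and _x_at probe sets there were 561, 1108 and 1844 at times 24, 48 and 96, 235 for the mock trend and 1874 for the difference in trend; MYCN turned to -0.72, -0.50, -1.45, -0.031, -0.57 and -0.60 over the 6 times, none of them called (adjusted p = 0.237 to 0.986), because its single responding probe set was left out and the next lies near background, and PPAT (-0.0012) and TCOF1 (-0.25) turned at time 192. Without the eBayes trend there were 58 at time 8 and 3 for the mock trend. Fits to the compared times alone gave 3 at time 8 and 544 at time 48, with fewer arrays. On log2(time + 1) the mock trend had 83; late minus early gave 2, and 1690 for the difference in trend. With an estimated correlation 0 of 160 list tests were called (limma camera; 34 unadjusted).

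With the replicate block 12, 280, 1773 and 2840 genes were called at times 4, 8, 24 and 48, and 4800 by the F-test. The numbers were taken to pair the arrays at times 4, 8 and 192, although the batch could give the same correlations. At those times the block moved no other count beyond 1.5 times. Of 67 list calls 65 were kept with the block; those lost were the MYC network at times 24 and 48, and those gained were cholesterol synthesis (adjusted p = 0.0274) and chaperones (0.0472) at time 8. All 21 arrays correlated best with arrays of their own number, a hint but no proof of shared handling.

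The batch as a block gave 3, 219, 1604 and 2696 at times 4, 8, 24 and 48. The ACTB covariate gave 2, 158 and 1574 at times 4, 8 and 24, and 0 for the mock trend (limma; 699 unadjusted). Without time 192 in either line the difference in trend had 1456.

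Leaving out arrays gave 1 to 2 at time 4, 2 to 75 at time 8, 164 to 726 at time 24, 241 to 2247 at time 48, 787 to 2794 at time 96, 1327 to 2972 at time 192, 687 to 3284 for the F-test, 1295 to 3291 for the difference in trend, 0 to 943 for the mock trend and 56 to 71 for lists. Counts moved without replicate 1 (4, 195, 359, 1449 and 1543 at times 8 to 192; F-test 857), replicate 2 (2, 164, 241, 787 and 1327; 687) and replicate 3 (21 at time 8). At time 8 the count was 55 and 16 without time 0 replicate 1 or 3, and 18, 12 and 33 without time 8 replicate 1, 2 or 3. Without time 0 replicate 1, or time 4 replicate 1 or 3, time 4 had 2. Time 24 had 555 without time 0 replicate 3, and 429 and 543 without its own replicate 1 or 2. Time 48 had 1121 without time 0 replicate 3, and 940 and 963 without its own replicate 1 or 2. The difference in trend had 1295 without the mock array of time 192. Without the mock arrays of times 0, 4, 8, 24, 48 and 192 the mock trend had 943, 0 (limma), 54, 136, 209 and 93. Signal over background limits the dim genes: folds that end below a signal of 12.8, where the filter lies, are uncertain in size.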

Other observations

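The tests of all times of batch 2 were chosen after the result was seen; those of batch at time 0 and of MYCN present before induction were chosen before their outcome was known, and the test of NRF2 target genes after the HMOX1 rise was seen but before the other targets were examined.

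The lines differed before doxycycline. At time 0, within batch 2, 335 genes differed by at least 2 (log2) between MYCN replicate 3 and the mock array, 141 higher and 194 lower in the MYCN line, against 55 between MYCN replicates 1 and 2. Among single genes, the transcription factor gene PHOX2A read 768 in the mock line against 1.4 in the MYCN line, HAND1 500 against 11, and the steroid enzyme HSD3B1 1487 against 1.7. The stress hormone gene CRH read 7044 against 15.2, and the cell cycle inhibitor gene CDKN2A 2800 against 17.5. Basement membrane collagens went the other way, with COL4A1 at 11.7 in the mock line against 1756 and COL4A2 at 17.6 against 1811, as did TAC1, at 40.3 against 1811. Of 28 noradrenergic markers 12 passed the signal filter, and these had a median difference of -1.17. The filter used the mean over both lines, so markers such as PHOX2A could pass through the mock arrays. The single genes named here were chosen after their values were seen, and with 1 mock array at time 0 no test of a gene was made.

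A batch effect was argued against by the spread of the difference, which was 1.89 times as wide as between MYCN replicates 1 and 2 although both arrays were in batch 2, and by 137 genes that differed by at least 2 in the same direction at all 7 times in that batch (42 higher and 95 lower in the MYCN line). MYCN itself was already present in the MYCN line at time 0 (69.4, 79.2 and 103 in the replicates, against 2.3, which is background, in the mock array). If MYCN were the cause of the other differences, they would resemble the late response, taken here as the mean change over the last 3 times. Genes are not independent replicates. Across them, the difference at time 0 correlated with that late change in replicates 1 and 2 at r = 0.0112 (Spearman rho 0.0580). This argues against leakage as the whole cause, but only for genes that further MYCN could still move. The late change starts from time 0, so a gene that leaked MYCN had already moved fully would not show it. A share from leakage therefore stays open. Of the genes called higher at time 192 in those replicates 58.8% were higher in the MYCN line at time 0, against 52.4% of all genes (median 0.10 against 0.025). The lists of mitochondrial ribosomal proteins (0.12 to 0.22), nucleotide synthesis (0.14 to 0.22) and chaperones (0.19 to 0.32) were higher than mock in all 3 replicates. Of the genes called lower at time 192 in replicates 1 and 2, 50.03% were lower in the MYCN line at time 0. Their median of -0.0017, against 0.025 for all genes, leaned slightly the way leakage would give. Against leakage, interferon response, which fell late, was also higher in all 3 replicates (0.31 to 0.39). DNA replication genes (0.47 to 0.59), which were not called late, were higher too. Their values cannot decide, since a leak that had already moved them fully would look the same. Ribosome biogenesis was mixed (0.26, 0.14 and -0.03). All these list differences were taken against the same single mock array, which shares a batch with replicate 3 alone, so the 3 replicates do not repeat the mock side. Separate clonal histories of the lines may account for the difference and stay untested, as does a sample of another origin.

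HMOX1 and SLC7A11, which rose late, are known targets of the oxidative stress factor NRF2, which led to the hypothesis that its targets rose together. Of 11 other measured targets, in a list written after the HMOX1 rise was seen, 7 were higher at time 192 and 1, PIR (-0.83), lower (limma), with a median of 0.456, against 0.185 at time 96 and -0.04 in the mock array of time 192. The list differed from other genes in limma's camera (p = 1.13e-04, and p = 0.00525 with an estimated correlation), unadjusted for the lists tested before. GCLM, a regulatory subunit of an enzyme of glutathione synthesis, rose by 0.94, and NQO1, a quinone reductase, by 0.46. Activation of NRF2 late after induction may account for this and remains a hypothesis, since HMOX1 itself varied widely between replicates (721 ± 624) and other stress pathways were not separated from it.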
